A study of Mus musculus with 4 samples.

How the data were processed

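The data were single-cell RNA-seq counts from pituitary glands of wild-type C57BL/6J male mice. The mice had eaten a control diet (CTRL) or a high-fat diet (HFD) for 12 weeks. Glands were digested separately into cell suspensions with collagenase and trypsin, per the labels' protocols, and run on a droplet platform (10x Genomics Chromium 3' v3.1) that tags the 3' end of polyadenylated RNA with a unique molecular identifier (UMI). There were 4 libraries, 2 for each diet, called CTRL 1, CTRL 2, HFD 1 and HFD 2. The labels do not say how many glands went into a library or whether libraries of one diet came from different animals. The p-values of genes and shares therefore measure only the spread between these samples, which may be technical.

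The deposited values were whole-number UMI counts per gene and barcode, not normalized, with 32285 genes in each matrix. Cell Ranger 6.1.2, Seurat 4.3 and the mouse build mm10 were named, without their roles, per the submitters' processing notes. The gene annotation and whether counting used the strand are not given in the sources used here. The lowest UMI total of a deposited barcode was 500. Counts of overlapping or antisense genes and of near-identical copies, such as the paired hemoglobin genes, are therefore uncertain. No cell annotation of the authors was used here, so all cell classes below were rebuilt and may differ from those of the study.

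Barcodes with at least 500 genes and at most 20% mitochondrial UMIs (13 mitochondrial genes) were taken as cells. Putative doublets were scored per library by the share of simulated doublets, 2 per cell, among each cell's nearest neighbours in 30 principal components. The highest scores were removed at an assumed rate of 0.8% per 1000 cells. Of 34737 barcodes, 1540 putative doublets were removed and 25680 cells were kept. Counts were scaled to 10000 UMIs per cell and log-transformed for clustering alone, with 2000 variable genes, 30 components, 20 neighbours and the Leiden method at resolution 0.8 (scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, Python 3.11.15).

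The 25 clusters were named from marker lists. A cluster took the class whose markers had the highest mean fold, if at least 3 of them were detected in 10% or more of its cells at a log2 fold of 1 or more, and the name carries "-like" because it rests on RNA alone. A first way of scoring, by the number of markers, gave a pericyte-like cluster the endothelial name and was replaced. That change, and a list of 3 clusters left unnamed for their leading genes, were made after the clusters had been seen and before any comparison of the diets. A total of 576 cells in 4 clusters stayed unnamed. Their leading genes were long nuclear RNAs, hemoglobin, Hmgb2 and tubulin genes in cells of few UMIs, genes of airway-type epithelium, and genes shared by monocytes and granulocytes. The unnamed share was 3.17% in CTRL 1, 1.2% in CTRL 2, 2.21% in HFD 1 and 2.73% in HFD 2. Granulocytes, red blood cells and cycling cells had marker lists and no named cluster.

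Cells are not replicates, so UMI counts were summed per library over all kept cells (the whole gland) and over each class with at least 30 cells in every library. There were 10 such classes. Pituicyte-like cells had 22 cells in CTRL 1 and were left out of the gene tests, as were the smaller classes. Sums were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F-test, with TMM scaling, the filterByExpr filter and Benjamini-Hochberg adjustment over the genes of one fit. An adjusted p under 0.05 counted as changed. Log2 values are HFD minus CTRL from the fit, and their standard errors (SE) were taken from the F statistic. Levels are CPM, the counts divided by the class total and scaled to 1e6, without TMM scaling, so their ratio can differ somewhat from the fitted change. Droplets also hold free RNA from broken cells. Genes whose CPM in a class was under 10% of their highest class were therefore counted apart as possible free RNA. Coordinates are those of GENCODE vM21 on mm10.

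The number of cells per class was tested in the same way with the number of kept cells as the library size, without TMM or a dispersion trend, and an exact two-sided permutation p was computed beside it. With 2 libraries against 2 that exact p cannot go below 0.333. Intervals of a share are exact 95% binomial intervals, which cover counting error only. Whether the diet effect differed between lactotrope-like and somatotrope-like cells was tested as an interaction with the library as a block. The 22 gene lists were tested in the 10 classes, 220 tests in all, by camera (limma 3.58.1) on voom log2 values with a preset correlation of 0.01. Camera compares listed genes with other genes, so with the preset its p does not measure the spread between libraries. An estimated correlation, and fry, were run beside it. With an estimated correlation camera also takes its degrees of freedom from the 4 libraries, so a list can fail there without strongly correlated genes. The test of fry's directional p asks whether a list's genes move on balance one way, without comparing them with other genes.

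The groups, tests, marker lists, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. By that rule the hormone genes and 13 regulators were named whatever their values. For each fit the rule then took genes with adjusted p under 0.05, both HFD libraries on one side of both CTRL libraries and at least 10% of the CPM of the highest class. The 10 higher and 10 lower genes with the smallest p were named in the whole gland and in the 3 classes with the most calls, and 3 of each in other classes. Where a class had none, the 3 genes with the smallest p were given as values that did not pass. Genes known only by clone-type names were counted and not named, and 2 to 4 members with the smallest p were named from each list. Hemoglobin genes and granulocyte markers in the whole gland, Cxcl12 in endothelial-like cells and Gm26737 in melanotrope-like cells were singled out after their values were seen.

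The alternatives were DESeq2's size factors within edgeR, the DESeq2 1.42.0 Wald test, no low-count filter, the replicate number as a block, each library left out in turn, cells with at least 1000 genes and at most 10% mitochondrial UMIs, putative doublets kept (24 clusters), and possible free RNA left out. For shares they also included limma on logit shares, hormone cells as the denominator, TMM on cell numbers and Leiden resolution 1.6 (35 clusters). Leaving out the 3 cells with over 100000 UMIs was added after seeing the data.

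The tests were tried on simulated data with the real means, spreads and library sizes, in which 200 genes were changed. The share of 2-fold changes recovered was 62% in the whole gland, 71% in somatotrope-like, 79% in lactotrope-like, 75% in corticotrope-like, 86% in gonadotrope-like and 72% in thyrotrope-like cells. It was 62% in melanotrope-like, 62% in stem-like, 58% in endothelial-like, 34% in macrophage-like and 3% in mesenchymal-like cells. False calls were above the nominal 5% in most simulations, with 32 of 211 calls in gonadotrope-like, 26 of 166 in the whole gland, 22 of 160 in endothelial-like and 16 of 173 in thyrotrope-like cells, so calls near the threshold are to be read with care. For shares, 91% of 2-fold changes in 3 classes were recovered over 200 simulated sets, at an assumed dispersion of 0.02, and 1.38% of unchanged classes were called. That dispersion lies below the spread of the real shares, with SE of 0.281 for lactotrope-like, 0.332 for stem-like and 0.345 for macrophage-like cells. The 91% therefore overstates what the test of the real shares could recover.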

Results

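Single-cell RNA-seq of the mouse pituitary was used to ask whether the makeup and gene expression of its cell populations differ after 12 weeks on a high-fat diet. The pituitary is the gland below the brain whose hormone cells each release mainly 1 hormone or hormone pair. Each diet had 2 libraries. The deposited barcodes held 92818116 UMIs in CTRL 1, 101903367 in CTRL 2, 74758237 in HFD 1 and 97223297 in HFD 2. Of 7463, 8173, 10921 and 8180 barcodes, 4350, 6904, 7498 and 6928 were kept as cells, in the same order. Barcodes under 500 genes made up 39.1% of CTRL 1, 10.1% of CTRL 2, 26.5% of HFD 1 and 9.69% of HFD 2. The median kept cell had 17962 UMIs in CTRL 1, 12444 in CTRL 2, 8631 in HFD 1 and 11057 in HFD 2. HFD 1 was the shallowest library, with 24.8% of its kept cells under 1000 genes, against 5.45%, 5.46% and 3.68% in CTRL 1, CTRL 2 and HFD 2. Adjusted p-values of genes below are Benjamini-Hochberg adjusted values of edgeR's quasi-likelihood test, with n = 2 libraries per diet throughout.

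The cells fell into 15 named classes. Somatotrope-like cells, which make growth hormone, were the most frequent with 8605 cells, followed by 5324 lactotrope-like (prolactin), 2485 corticotrope-like (Pomc, the precursor of ACTH) and 2001 melanotrope-like cells of the intermediate lobe. There were 1658 stem-like, 1436 gonadotrope-like, 1162 endothelial-like, 783 thyrotrope-like, 555 macrophage-like and 468 mesenchymal-like cells. Pituicyte-like (228), T or NK cell-like (171), pericyte-like (124), B cell-like (55) and Schwann or glia-like cells (49) were counted and not tested for genes. The class sums ranged from 33761788 UMIs (somatotrope-like, HFD 2) to 579904 (mesenchymal-like, HFD 1).

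Lactotrope-like, melanotrope-like and endothelial-like cells took smaller shares of both HFD libraries than of both CTRL libraries. Corticotrope-like, gonadotrope-like and pituicyte-like cells took larger ones. Lactotrope-like cells made up 24.3% ± 3.62 (SD, n = 2) of CTRL and 17.4% ± 1.88 of HFD cells, and melanotrope-like cells 10.0% ± 3.52 and 5.58% ± 1.05. Gonadotrope-like cells made up 4.12% ± 1.13 and 6.83% ± 1.96, and corticotrope-like cells 8.91% ± 0.0817 and 10.3% ± 0.583. Endothelial-like cells made up 5.26% ± 0.259 and 3.90% ± 0.557, and pituicyte-like cells 0.637% ± 0.185 and 1.06% ± 0.029. Somatotrope-like cells made up 30.3% ± 3.16 of CTRL and 36.6% ± 6.57 of HFD cells, and the ranges of the diets overlapped.

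The share differences did not pass the test. The log2 ratios of HFD over CTRL were -0.85 (SE 0.35) for melanotrope-like, 0.73 (SE 0.36) for gonadotrope-like and 0.71 (SE 0.34) for pituicyte-like cells, each at an edgeR adjusted p of 0.419. They were -0.48 (SE 0.28) for lactotrope-like and -0.43 (SE 0.28) for endothelial-like cells (edgeR adjusted p = 0.514 each), 0.21 (SE 0.26) for corticotrope-like cells (edgeR adjusted p = 0.632) and 0.27 (SE 0.29) for somatotrope-like cells (edgeR adjusted p = 0.601). Leaving out 1 library moved these values. They ranged from -1.17 (without CTRL 1) to -0.43 (without CTRL 2) for melanotrope-like, 0.41 (without HFD 1) to 1.04 (without CTRL 1) for gonadotrope-like, 0.46 (without CTRL 1) to 1.06 (without CTRL 2) for pituicyte-like, -0.62 (without CTRL 1) to -0.32 (without CTRL 2) for lactotrope-like and 0.07 (without HFD 2) to 0.44 (without HFD 1) for somatotrope-like cells. The gonadotrope-like value was 0.47 without CTRL 2, and the somatotrope-like value 0.17. The exact two-sided permutation p of a class without overlap was 0.333, the smallest that 2 libraries against 2 allow. Stem-like (0.07), thyrotrope-like (0.31), macrophage-like (0.09) and mesenchymal-like cells (0.41) had overlapping shares and a change of sign when 1 library was left out. Without CTRL 2 the values were -0.05 for stem-like, -0.002 for thyrotrope-like and -0.25 for macrophage-like cells, without HFD 1 -0.31 for stem-like, and without HFD 2 -0.02 for mesenchymal-like cells. Among rare classes the log2 ratio was 0.07 for T or NK cell-like cells, from 0.009 without HFD 1 to 0.13 without HFD 2, with 0.03 without CTRL 1 and 0.13 without CTRL 2. It was -0.36 for pericyte-like cells, -0.04 without CTRL 2, -0.07 without HFD 1, -0.58 without CTRL 1 and -0.71 without HFD 2. It was 0.17 for B cell-like cells, -0.28 without CTRL 2 and -0.21 without HFD 1, and 1.33 for Schwann or glia-like cells, -1.33 without HFD 2.

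Among gonadotrope-like, melanotrope-like and corticotrope-like cells, clusters of few UMIs drew most of their cells from the shallow library, HFD 1. Unnamed clusters of few UMIs did not. The cluster of median 1326 UMIs drew 98 of 201 cells from CTRL 1, and that of median 2223 drew 127 of 277 from HFD 2. A gonadotrope-like cluster of few UMIs (median 1494) drew 82.9% of its 538 cells from HFD 1, and such clusters among melanotrope-like and corticotrope-like cells drew 68.6% and 55.5%. Stem-like, thyrotrope-like and pituicyte-like cells of HFD 1 were shallow as well, at medians of 2058, 2301 and 1420 UMIs. In the other libraries their medians were at least 11127.5, 14623 and 13368. With only cells of at least 1000 genes and at most 10% mitochondrial UMIs, limits that were changed together, gonadotrope-like cells made up 4.93% of CTRL 1, 3.01% of CTRL 2, 3.43% of HFD 1 and 5.28% of HFD 2, a log2 ratio of 0.14. Pituicyte-like cells made up 0.464%, 0.676%, 0.552% and 0.844%, a log2 ratio of 0.28, so the diets overlapped for these classes. Somatotrope-like shares no longer overlapped, at 34.0% of CTRL 1, 29.2% of CTRL 2, 41.1% of HFD 1 and 42.7% of HFD 2. Neither did those of T or NK cell-like cells, at 0.586%, 0.645%, 0.907% and 0.678%. Their log2 ratios of 0.41 and 0.36 did not pass (edgeR adjusted p = 0.877 each). The log2 ratio was 0.09 for corticotrope-like, -0.17 for pericyte-like, -1.27 for melanotrope-like, 0.06 for thyrotrope-like and 0.19 for macrophage-like cells. It was -0.15 for stem-like and -0.12 for B cell-like cells, opposite in sign to the ratio of all kept cells.

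**Figure D1:**
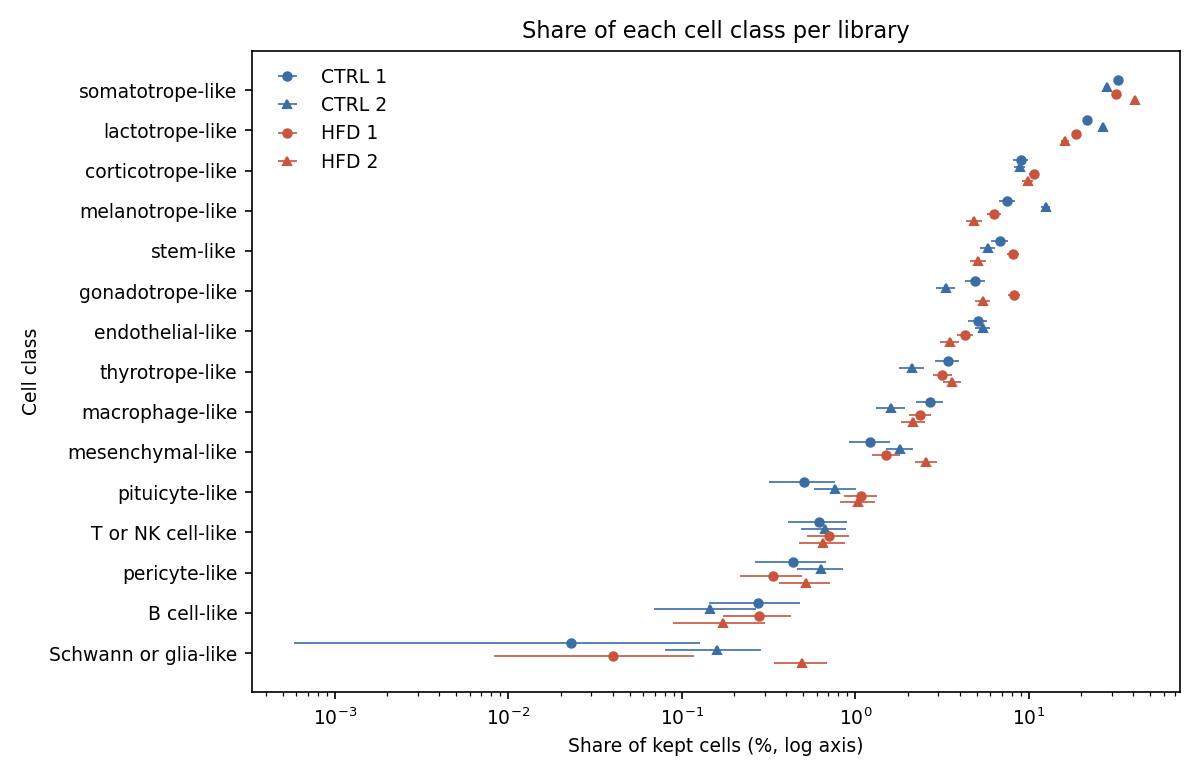
Share of kept cells in each class (percent, log axis) for the 4 libraries, with exact binomial 95% intervals that cover counting error only. Lactotrope-like cells averaged 24.3% of CTRL and 17.4% of HFD cells, without a passed test.

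In the whole gland, S100a8 and S100a9, which encode the subunits of calprotectin, an abundant protein of neutrophils, were far higher in both HFD libraries. S100a8 (ENSMUSG00000056054, chromosome 3, 90668978 to 90670035) had 39.0 ± 0.842 CPM in HFD and 0.0113 ± 0.000665 in CTRL, and S100a9 (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721) 46.7 ± 10.4 and 0.00588 ± 0.00832. The CTRL libraries held 2 UMIs of S100a8 and 1 of S100a9, so the ratios of 3470 and 8097 had 95% counting intervals from 960.1 to 28660 and from 1453 to 319900. These intervals treat each UMI as independent and are too narrow, since nearly all HFD UMIs lay in 7 cells per library. S100a8 and S100a9 were the 2 genes that passed out of 18531 (edgeR adjusted p = 1.25e-05 and 0.000571), with 1953 genes at unadjusted p under 0.05 and 214 passing by DESeq2. Both also passed without any 1 library, with the lone library of a diet assumed to vary like the other diet, while the number of genes passing was 8 without CTRL 1, 6 without CTRL 2, 89 without HFD 1 and 336 without HFD 2. The log2 difference of 12.64 was 11.71 without CTRL 2 (S100a9, whole gland), and none is given without CTRL 1, since CTRL 2 held 0 UMIs of that gene.

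The UMIs of both genes lay in few cells. In each HFD library 7 cells with at least 5 of these UMIs held 99.5% (HFD 1) and 99.0% (HFD 2) of them. Other granulocyte markers were at low levels. Retnlg was at 0 CPM in both CTRL libraries and at 8.12 and 2.52 in HFD 1 and HFD 2, Csf3r averaged 0.34 ± 0.0677 in CTRL and 0.827 ± 0.106 in HFD, and Cxcr2 0.156 ± 0.0706 and 0.413 ± 0.132. None of these 3 passed (edgeR adjusted p from 0.199 to 0.425). Hemoglobin transcripts were also higher in both HFD libraries, without passing in the fit of all 4 libraries. Hbb-bs averaged 271.1 ± 58.6 CPM in CTRL and 943.5 ± 8.27 in HFD (edgeR adjusted p = 0.115), and Hbb-bt 30.7 ± 5.78 and 154.8 ± 18.7 (edgeR adjusted p = 0.0658). The difference (Hbb-bs, whole gland) passed when any 1 library was left out (log2 2.03 without CTRL 1, 1.53 without CTRL 2, 1.76 without HFD 1, 1.75 without HFD 2), and that of Hbb-bt without CTRL 1 (2.53), HFD 1 (2.43) or HFD 2 (2.15).

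Among the hormone genes, those of 2 gonadotropin subunits rose in their own class. Cga, the common alpha subunit of the glycoprotein hormones, rose in gonadotrope-like cells, with a log2 difference of 0.54 (SE 0.07, edgeR adjusted p = 0.0121). Fshb, the beta subunit of follicle-stimulating hormone (chromosome 2, 107056140 to 107059656), averaged 12480 ± 1464 and 15420 ± 155.6 CPM, a log2 difference of 0.45 (SE 0.07, edgeR adjusted p = 0.0204). Lhb, the beta subunit of luteinizing hormone, averaged 1412 ± 682 and 512.1 ± 388.8 CPM (log2 -1.31, SE 0.45, edgeR adjusted p = 0.127). The difference (Lhb, gonadotrope-like cells) passed without HFD 2 alone (-2.42, edgeR adjusted p = 0.000614) and its value was -0.73 without CTRL 1 and -0.71 without HFD 1.

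The other hormone genes did not pass. Gh averaged 409400 ± 38540 CPM in CTRL and 361400 ± 21280 in HFD somatotrope-like cells (log2 -0.34, SE 0.11, edgeR adjusted p = 0.206). Prl averaged 222800 ± 27370 and 182600 ± 46170 in lactotrope-like cells (log2 -0.33, SE 0.16, edgeR adjusted p = 0.480), and -0.67 without HFD 2 passed (edgeR adjusted p = 0.00187). The values for Pomc, corticotrope-like cells, averaged 66040 ± 16180 and 72620 ± 5728 (log2 0.22, SE 0.15, edgeR adjusted p = 0.635), and 0.49 without CTRL 1 passed (edgeR adjusted p = 7.74e-05). In melanotrope-like cells Pomc averaged 174100 ± 29130 and 192200 ± 25670 (log2 0.21, SE 0.16, edgeR adjusted p = 0.770). In thyrotrope-like cells Tshb, the beta subunit of thyrotropin, averaged 33440 ± 1506 and 38930 ± 678.8 (log2 0.23, SE 0.06, edgeR adjusted p = 0.246). The other subunit (Cga, thyrotrope-like cells) had a log2 difference of 0.23 (SE 0.07, edgeR adjusted p = 0.388), and 0.32 without CTRL 2 passed (edgeR adjusted p = 9.2e-05).

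**Figure D2:**
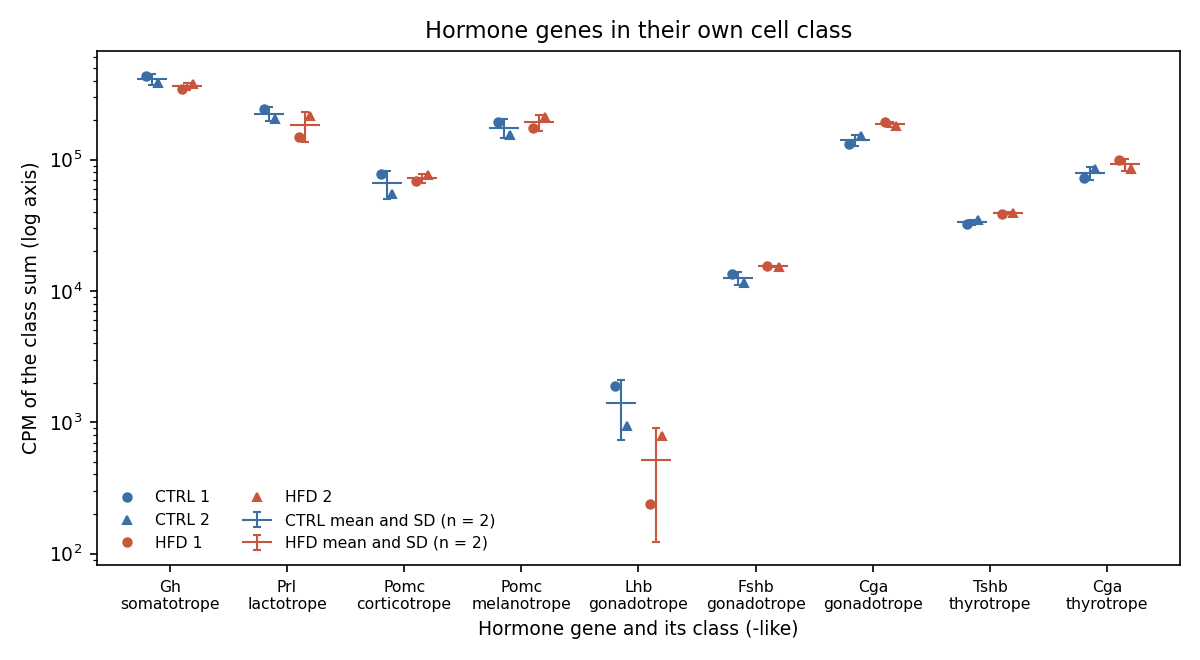
Level of each hormone gene in its own class (CPM of the class sum, log axis) per library, with the mean and SD of n = 2 libraries per diet. Fshb in gonadotrope-like cells averaged 12480 CPM in CTRL and 15420 in HFD.

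The 13 regulators named in advance were tested in 69 pairs of gene and class, and the smallest edgeR adjusted p was 0.0538, for the gonadotropin-releasing hormone receptor Gnrhr in gonadotrope-like cells. Gnrhr averaged 1217 ± 258.8 CPM in CTRL and 755.4 ± 28.6 in HFD (log2 -0.55, SE 0.13), and it passed without CTRL 1 (-0.76, edgeR adjusted p = 0.000177). The thyrotropin-releasing hormone receptor Trhr averaged 76.9 ± 3.32 and 109.0 ± 5.59 CPM in thyrotrope-like cells (log2 0.50, SE 0.11, edgeR adjusted p = 0.0734), and 0.52 without CTRL 2 passed (edgeR adjusted p = 0.0401). The growth hormone-releasing hormone receptor Ghrhr averaged 83.8 ± 8.37 and 93.1 ± 11.1 CPM in somatotrope-like cells (log2 0.004, SE 0.12, edgeR adjusted p = 0.990), -0.04 without CTRL 1 and -0.17 without HFD 2. In the class of their highest level, log2 differences were 0.48 for the somatostatin receptor Sstr5 (somatotrope-like), -0.49 for Sstr2 (thyrotrope-like), 0.08 for the dopamine receptor Drd2 (melanotrope-like) and 0.39 for the glucocorticoid target Fkbp5 (mesenchymal-like). Values near 0 that changed sign with 1 library left out were Crhr1 (corticotrope-like, -0.06, and 0.01 without CTRL 2), the leptin receptor Lepr (endothelial-like, -0.07, 0.03 without CTRL 1 and 0.09 without HFD 2), Igf1r (stem-like, -0.04, and 0.01 without HFD 2) and the transcription factor Pou1f1 (lactotrope-like, -0.06, and 0.07 without HFD 2). The ghrelin receptor Ghsr was at -0.46 in corticotrope-like cells and 0.03 without CTRL 1, and the insulin receptor Insr at 0.36 in endothelial-like cells. The edgeR adjusted p of these 10 lay between 0.193 and 0.999.

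In somatotrope-like cells Csrnp1, Btg2 and Rasd1 fell in HFD and Scnn1b rose. Csrnp1, a cysteine- and serine-rich nuclear protein (chromosome 9, 119971163 to 119984658), averaged 25.1 ± 0.339 CPM in CTRL and 7.93 ± 0.192 in HFD (log2 -1.82, SE 0.10, edgeR adjusted p = 0.00741). Btg2, an antiproliferative immediate-early gene (chromosome 1, 134075170 to 134079120), averaged 798.5 ± 45.0 and 334.8 ± 38.9 (log2 -1.41, SE 0.12, edgeR adjusted p = 0.0398). Rasd1, a dexamethasone-induced Ras protein (chromosome 11, 59963181 to 59964944), averaged 140.5 ± 3.68 and 56.7 ± 12.7 (log2 -1.47, SE 0.13, edgeR adjusted p = 0.0398). Scnn1b, the beta subunit of the epithelial sodium channel (chromosome 7, 121865038 to 121918514), averaged 23.2 ± 1.04 and 48.2 ± 4.398 (log2 0.90, SE 0.08, edgeR adjusted p = 0.0398).

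Of 14560 genes, 7 passed, 1 higher and 6 lower, among them 3 of possible free RNA (Neat1, Gadd45b and Serpinh1). A total of 2682 genes were at unadjusted p under 0.05, and DESeq2 called 382. The cells came from different clusters in the diets. Cluster 0, with Scnn1b among its leading genes, gave 305 and 281 cells of CTRL 1 and CTRL 2 and 1730 and 1716 of HFD 1 and HFD 2. Cluster 2, led by Dnajb1 and with Fos, Egr1 and Egr2 among its leading genes, gave 476, 1063, 405 and 608, and cluster 3 gave 636, 596, 258 and 531. The calls needed both CTRL libraries. Without CTRL 1 or without CTRL 2 there were 0 calls by edgeR, with adjusted p of 0.0753 and 0.111 (Csrnp1, somatotrope-like), Btg2 0.108 and 0.159, Rasd1 0.115 and 0.159 and Scnn1b 0.122 and 0.159, against 6 calls without HFD 1 (Scnn1b lost at 0.0729) and 86 without HFD 2. Without a low-count filter 1 gene passed, and Btg2, Rasd1 and the rise (Scnn1b, somatotrope-like cells) stood at an edgeR adjusted p of 0.0884.

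Immediate-early genes, which are induced within minutes of a stimulus and also by tissue dissociation, were lower as a list in HFD in 4 hormone classes. The median log2 difference was -1.30 over 24 measured genes in somatotrope-like cells (camera adjusted p = 1.05e-16), -0.94 over 24 in gonadotrope-like cells (1.94e-20), -0.78 over 24 in thyrotrope-like cells (1.48e-30) and -0.29 over 25 in lactotrope-like cells (2.12e-06). None of these 4 calls held with an estimated correlation (camera adjusted p = 0.674 in each). In gonadotrope-like cells that correlation was -0.003, below the preset 0.01, and the unadjusted camera p still went from 1.76e-22 to 0.00841. The loss of the call there does not come from correlated genes. The estimate was 0.407 in somatotrope-like, 0.32 in thyrotrope-like and 0.084 in lactotrope-like cells. Genes passing edgeR numbered 2 in somatotrope-like, 12 in gonadotrope-like, 9 in thyrotrope-like and 2 in lactotrope-like cells, all lower, and adjusted over the list alone 20, 23, 19 and 9.

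Fos, a subunit of the AP-1 transcription factor, and the transcription factor Egr1 fell in gonadotrope-like cells (log2 -0.65 and -0.81), with Socs3, a feedback inhibitor of cytokine signalling (-1.91). In thyrotrope-like cells the transcription factor Klf2 fell by 2.47 on the log2 scale (-1.85 without CTRL 1 and -3.20 without HFD 2 for Klf2, thyrotrope-like cells) and Socs3 fell by 1.20. Socs3 in both classes and Klf2 stood under 10% of their highest class and are possible free RNA. The summed level of the list was 8544 and 12360 CPM in CTRL and 5156 and 6144 in HFD somatotrope-like cells, 5724 and 5642 against 3258 and 3436 in gonadotrope-like cells, and 6087 and 5488 against 3854 and 3671 in thyrotrope-like cells. In the remaining classes the list did not pass, with medians of -0.20 in corticotrope-like, -0.25 in melanotrope-like, 0.03 in stem-like, -0.02 in endothelial-like, 0.07 in macrophage-like and 0.01 in mesenchymal-like cells. In corticotrope-like cells 1 member, the stress-induced Ier3, rose in the fit of all 4 libraries (log2 2.11, edgeR adjusted p = 0.00104), and it is possible free RNA there at 3.1% of its highest class.

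**Figure D3:**
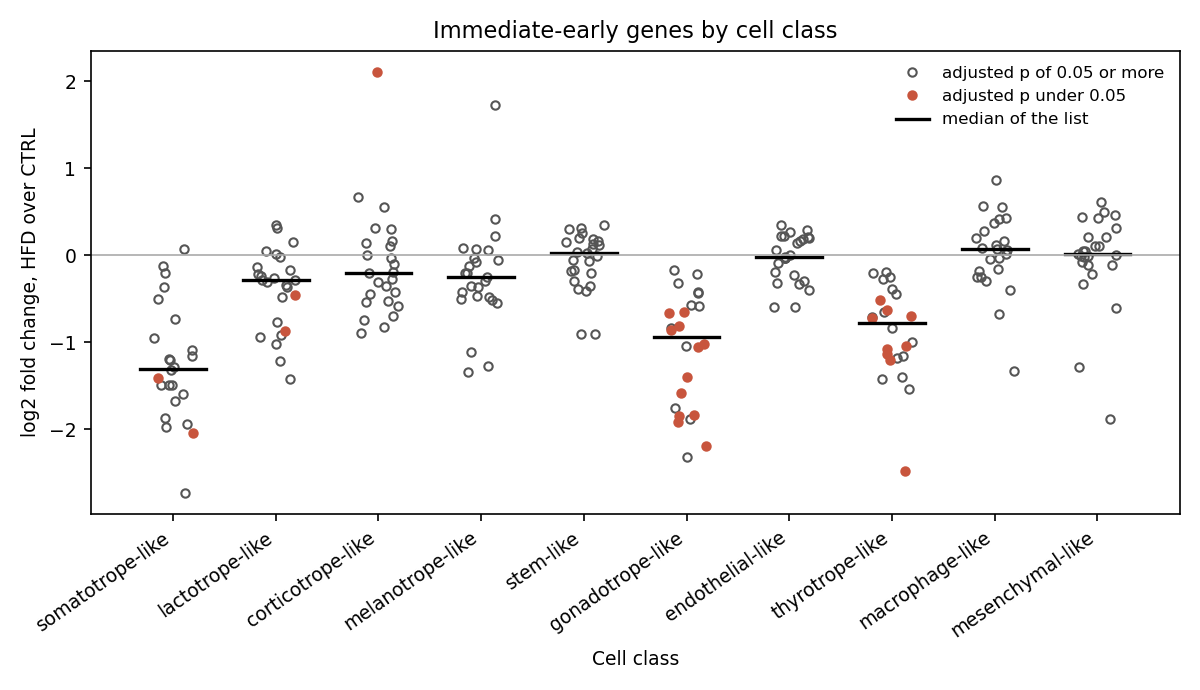
Log2 difference (HFD minus CTRL) of each gene of the immediate-early list in each class, with filled points at an edgeR adjusted p under 0.05 and a black line at the list's median. The median was -1.30 in somatotrope-like and 0.03 in stem-like cells.

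The heat shock list was lower in gonadotrope-like (median log2 -0.45, camera adjusted p = 5.05e-07), somatotrope-like (-0.57, 2.61e-06) and thyrotrope-like cells (-0.15, 5.34e-05) and higher in corticotrope-like cells (0.18, 0.00248). It did not pass in lactotrope-like cells (0.002, 0.900). The adjusted p was 0.674 with an estimated correlation, and 0.772 in thyrotrope-like cells. In gonadotrope-like cells 4 of 16 measured members fell and 8 adjusted over the list alone, among them the HSP70 cochaperone Dnajb1 (-1.30) and the HSP70 exchange factor Hsph1 (-0.70). In somatotrope-like cells 0 members passed edgeR, 9 adjusted over the list alone, and Dnajb1 stood at -1.15 (edgeR adjusted p = 0.125). In thyrotrope-like cells Dnajb1 fell (-1.30), 2 genes passing adjusted over the list alone, and in corticotrope-like cells the cochaperone Bag3 rose (0.98) in the fit of all 4 libraries, the 1 gene that also passed adjusted over the list alone.

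In lactotrope-like cells Wfdc2, a secreted WAP-domain protein (chromosome 2, 164562413 to 164568510), rose from 99.5 ± 8.27 to 230.7 ± 37.2 CPM (log2 1.16, SE 0.11, edgeR adjusted p = 0.000197). Akr1c14, a hydroxysteroid dehydrogenase and 1 of the markers used to name the class (chromosome 13, 4049011 to 4090688), fell from 33.7 ± 7.52 to 9.22 ± 2.26 CPM (log2 -1.92, SE 0.19, edgeR adjusted p = 0.000295). Rasd1 fell from 117.9 ± 12.9 to 57.5 ± 2.51 CPM (log2 -1.09, SE 0.11, edgeR adjusted p = 0.000403). The matricellular protein Ccn3 fell from 24.2 ± 3.13 to 4.82 ± 2.60 CPM (log2 -2.37, SE 0.26, edgeR adjusted p = 0.000727).

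Also higher were the efflux transporter Abcb1b (log2 1.18), Thsd7b (2.04), the bHLH transcription factor Atoh7 (1.67), the BMP antagonist Nog (1.35), the fructose-2,6-bisphosphatase Tigar (0.82), the mitochondrial amidotransferase subunit Gatb (0.93), the secreted glycoprotein Olfm1 (0.68), fibulin-3 (Efemp1, 0.65) and the paraoxonase Pon2 (0.71). Also lower were Slc35f4 (-3.85), the endothelin-converting-enzyme-like Ecel1 (-0.82), the ankyrin Ank1 (-0.90), the cytochrome c oxidase subunit Cox7a1 (-1.72), the calcium-binding calbindin (Calb1, -1.13), Olfm3 (-1.64) and the forkhead factor Foxq1 (-1.48). Their edgeR adjusted p lay between 0.000727 and 0.00746. Of 13699 genes 168 passed, 73 higher and 95 lower, 51 of them possible free RNA. A total of 1523 were at unadjusted p under 0.05, and DESeq2 called 154. The number was 128 without CTRL 1, 50 without CTRL 2, 255 without HFD 1 and 493 without HFD 2, and 85, 32, 130 and 151 of these were among the 168. Without CTRL 2, 13 of the 20 named genes passed and the edgeR adjusted p was 0.0599 (Atoh7, lactotrope-like cells), 0.0647 for Olfm1, 0.0684 for Efemp1, 0.0835 for Cox7a1, 0.0924 (Pon2, lactotrope-like cells), 0.0989 for Olfm3 and 0.120 for Foxq1. The log2 difference (Slc35f4, lactotrope-like cells) was -3.02 without HFD 1 and -5.80 without HFD 2, and another (Ccn3, lactotrope-like cells) -3.11 without HFD 2.

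Whether the diet effect differed between lactotrope-like and somatotrope-like cells was tested directly. Lpl, the lipoprotein lipase that releases fatty acids from triglycerides, had a log2 difference of 1.05 in lactotrope-like and -1.05 in somatotrope-like cells, a difference of effects of 2.07 (SE 0.15, edgeR adjusted p = 0.00332). The fatty acid-binding protein Fabp5 went the other way, with -0.92 in lactotrope-like and 0.67 in somatotrope-like cells (difference -1.58, edgeR adjusted p = 0.00332; possible free RNA in both), as did the adhesion molecule Ntm with -1.36 and 0.63 (-1.99, edgeR adjusted p = 0.0053). Dusp1, an immediate-early phosphatase, had -0.14 in lactotrope-like and -1.98 in somatotrope-like cells, a difference of 1.92.

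Of 15282 genes, 126 differed, 70 with the larger value in lactotrope-like cells and 56 in somatotrope-like cells, and 2336 were at unadjusted p under 0.05. At least 1 of the 2 classes held 110 of the 126 at 10% or more of their highest class, and the rest are possible free RNA. Genes picked for a large difference of effects tend to have opposite signs, so the next split was largely fixed in advance. Of the 126, 58 were lower in somatotrope-like and higher in lactotrope-like cells, 55 were the reverse and 13 had 1 sign. The number was 105 without CTRL 1, 76 without CTRL 2, 99 without HFD 1 and 643 without HFD 2. Genes named in either class that differed were Csrnp1 (1.69), Btg2 (0.92), Nog (1.84), Atoh7 (2.43) and Tigar (1.08). The edgeR adjusted p was 0.0689 for Atoh7 without CTRL 2, and for Tigar 0.106 without CTRL 1 and 0.0858 without CTRL 2.

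In gonadotrope-like cells the neuropilin Nrp2, the transcriptional regulator Hes6, the BMP antagonist Grem1 and the stress-induced Nupr1 rose, and Dnajb1, Fos and Egr1 fell. Nrp2, a receptor of semaphorins, rose from 47.5 ± 10.6 to 106.2 ± 3.68 CPM (log2 1.30, SE 0.13, edgeR adjusted p = 0.00443). Dnajb1 fell from 271.7 ± 44.1 to 99.7 ± 11.0 CPM (log2 -1.30, SE 0.11, edgeR adjusted p = 0.00223). The log2 difference was 0.57 for Hes6, 0.65 for Grem1 and 1.06 for Nupr1. Also higher were Ly6h (0.56), Speer4e (0.99), the LIM protein Csrp2 (0.96), Serpina3c (1.82), the mitochondrial calcium uniporter subunit Mcub (0.73) and Cga. Also lower were the cold-inducible RNA-binding protein Rbm3 (-0.69), Fos (-0.65), the tight junction protein Cldn7 (-0.75), Sh3pxd2a (-0.99), Zfp507 (-1.25), the activity-dependent transcription factor Npas4 (-1.55), Egr1 (-0.81), the calcium pump Atp2a2 (-0.63) and the cyclin Ccnl1 (-0.81). The edgeR adjusted p of these 20 genes lay between 0.00223 and 0.0187, and all 20 also passed without any 1 library.

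Of 12661 genes 322 passed, 184 higher and 138 lower, 53 of them possible free RNA, including 4 hemoglobin genes among the higher ones. A total of 2968 were at unadjusted p under 0.05, and DESeq2 called 242. The number was 751 without CTRL 1, 267 without CTRL 2, 171 without HFD 1 and 194 without HFD 2, with 276, 161, 136 and 122 of the 322 among them. The class held cluster 9, with 198, 184, 170 and 346 cells of CTRL 1, CTRL 2, HFD 1 and HFD 2, and the low-UMI cluster 12, with 16, 45, 446 and 31.

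In thyrotrope-like cells the calcium-binding parvalbumin (Pvalb, chromosome 15, 78191114 to 78206400) rose from 42.0 ± 6.64 to 97.4 ± 1.70 CPM (log2 1.24, SE 0.13, edgeR adjusted p = 7.12e-05). The metallothionein Mt3 (0.74), Txnip, an inhibitor of thioredoxin (0.81), the cell cycle inhibitor Cdkn1c (1.09), neuroglobin (Ngb, 1.14) and the noncoding Snhg11 (0.66) also rose, at edgeR adjusted p from 0.000989 to 0.0153. Hemoglobin transcripts, made by red blood cells, also passed in this class, with Hbb-bt at 2.53 ± 0.163 CPM in CTRL and 362.6 ± 266.1 in HFD and Hbb-bs at 23.1 ± 6.54 and 2566 ± 2730 (log2 7.09 and 6.76). They held between 20.2% (CTRL 1) and 74.8% (HFD 2) of the UMIs in barcodes under 500 genes, and with no red blood cell class named the 10% rule could not count them as free RNA, so these values are not taken as a change in the class. The log2 differences of Hba-a1 and Hba-a2 were 6.70 and 6.98. Leaving out 1 library changed them to 6.08 without HFD 1 and 7.73 without HFD 2 (Hbb-bt, thyrotrope-like), 4.74 and 7.57 (Hbb-bs, thyrotrope-like), 5.06 and 7.47 (Hba-a1, thyrotrope-like), and 5.12, 7.81 and, without CTRL 1, 7.99 (Hba-a2, thyrotrope-like).

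Lower in the same class were Dnajb1 (-1.30), Fos (-0.63), Junb (-0.72), Egr1 (-0.70), the histone gene Hist2h2aa1 (-1.40, and -2.35 without HFD 2 for Hist2h2aa1, thyrotrope-like), Rasd1 (-0.63), Errfi1 (-0.77), Ier2 (-0.51), Zfp36 (-1.04) and Rbm3 (-0.50), at edgeR adjusted p from 0.000333 to 0.0418. Other settings ended calls as well. The adjusted p by DESeq2 was 0.449 for Cdkn1c, 0.110 for Ngb, 0.670 for Errfi1, 1 for Hist2h2aa1, 1 for Zfp36 and 0.0507 for Snhg11, thyrotrope-like. With putative doublets kept, the edgeR adjusted p was 0.0603 for Egr1 and Hist2h2aa1 and 0.0962 for Junb, thyrotrope-like. With the stricter cell filter it was 0.137 for Ier2, 0.127 for Zfp36, 0.0789 for Rbm3 and 0.0567 for Errfi1. Of the 20 named genes 10 passed in each setting other than leaving out a library. These 10 include the 4 hemoglobin genes, which are not taken as a change in the class. The counts out of 20 given below include them too. Of 11515 genes 45 passed, 17 higher (4 of them hemoglobin genes and 1 Alas2, of heme synthesis in red blood cells) and 28 lower, 16 of them possible free RNA. A total of 850 were at unadjusted p under 0.05, and DESeq2 called 23. The number was 78 without CTRL 1, 202 without CTRL 2, 95 without HFD 1 and 51 without HFD 2. Without HFD 2, 14 of the 20 named genes passed and Zfp36 was at -0.48 (edgeR adjusted p = 0.389), Ier2 at 0.152, Snhg11 at 0.152, Rasd1 at 0.136, Errfi1 at 0.108 and Rbm3 at 0.108. Without CTRL 1, 16 passed (Rbm3 0.293, Snhg11 0.0777, Errfi1 and Ier2 0.0512), and without CTRL 2, 18 (0.0756 for Ier2, and 0.0584 for Rasd1, thyrotrope-like cells).

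In corticotrope-like cells C2cd4b, a nuclear protein induced by inflammatory cytokines (chromosome 9, 67759437 to 67760930), rose from 197.8 ± 7.28 to 466.2 ± 35.1 CPM (log2 1.32, SE 0.11, edgeR adjusted p = 0.00104). The orphan receptor Gprc5a (log2 1.76) and the stress-induced Gadd45a (0.87) rose too. The clock gene Dbp fell from 114.4 ± 22.6 to 48.9 ± 1.87 CPM (log2 -1.14, SE 0.14, edgeR adjusted p = 0.0151), with Per3 (-0.74). Rasd1 rose (0.83) in the fit of all 4 libraries, with an edgeR adjusted p of 0.017. Of 12575 genes 31 passed, 26 higher and 5 lower, 6 of them possible free RNA. A total of 1263 were at unadjusted p under 0.05, and DESeq2 called 70. The number was 271 without CTRL 1, 917 without CTRL 2, 3 without HFD 1 and 5 without HFD 2. Of the 31, 3 passed without HFD 1 and 3 without HFD 2, and of C2cd4b, Gprc5a, Gadd45a, Dbp and Per3, C2cd4b alone passed without either HFD library. Without HFD 1 and without HFD 2 the edgeR adjusted p was 0.152 and 0.105 for Gprc5a, 0.271 and 0.122 for Gadd45a, 0.166 and 0.178 for Dbp and 0.441 and 0.247 for Per3.

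Circadian clock genes were lower as a list in corticotrope-like cells (median log2 -0.28 over 18 genes, camera adjusted p = 0.00313) and higher in lactotrope-like cells (0.19 over 18, 0.0154). The adjusted p was 0.674 and 0.738 with an estimated correlation. In corticotrope-like cells Dbp and Per3 fell and Arntl rose (0.89) in the fit of all 4 libraries, 2 higher and 6 lower passing adjusted over the list alone. In lactotrope-like cells 0 members passed edgeR and 7 higher and 2 lower adjusted over the list alone, with Per2 at 1.09 (edgeR adjusted p = 0.0555) and Arntl at -0.67 (0.0789).

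In melanotrope-like cells 1 gene passed, the noncoding Gm26737, annotated as antisense (chromosome 9, 44112923 to 44121960), which rose from 0.29 ± 0.183 to 21.4 ± 8.90 CPM (log2 6.32, SE 0.50, edgeR adjusted p = 0.00549). The value for Gm26737, melanotrope-like cells, was 6.96 without CTRL 1 and 5.54 without CTRL 2. It was singled out after its values were seen, and UMIs of a gene on the other strand cannot be excluded. The smallest p otherwise were those of the GTPase Rrad (2.13), Ier3 (1.73) and Avpi1 (1.00), at edgeR adjusted p of 0.248, 0.347 and 0.348. Each passed in some fits with 1 library left out, 1 (Rrad, melanotrope-like) with values from 1.72 (without HFD 1) to 2.53 (without CTRL 1), another (Ier3, melanotrope-like) from 1.29 (without CTRL 2) to 2.29 (without CTRL 1) and Avpi1 with 1.23 without CTRL 2, 1.15 without HFD 1 and 0.83 without HFD 2. A total of 933 genes were at unadjusted p under 0.05, DESeq2 called 9, and the number was 7 without CTRL 1, 195 without CTRL 2, 41 without HFD 1 and 44 without HFD 2.

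In macrophage-like cells the monocyte-attracting chemokine Ccl8 (chromosome 11, 82115185 to 82116799) rose from 9.26 ± 6.03 to 103.5 ± 38.6 CPM (log2 3.58, SE 0.41, edgeR adjusted p = 0.0276), and for Ccl8, macrophage-like cells, the value was 2.95 without CTRL 1 and 4.38 without CTRL 2. It was the 1 gene of 7452 that passed, with 444 at unadjusted p under 0.05 and 1 by DESeq2, and the number was 13 without CTRL 1, 7 without CTRL 2, 13 without HFD 1 and 15 without HFD 2. In endothelial-like cells the chemokine Cxcl12 was the 1 gene that passed (16.2 ± 1.73 to 86.5 ± 9.71 CPM, log2 2.43, SE 0.21, edgeR adjusted p = 0.031). It was singled out after its values were seen, stood at 9.8% of its highest class, and did not pass with the stricter cell filter (0.0789) or with doublets kept (0.136). Igkc (5.65, edgeR adjusted p = 0.419) and Ly6d did not pass, Ly6d at 0 CPM in both CTRL libraries and at 9.76 and 8.87 in HFD 1 and HFD 2. Both lead the B cell-like cluster. Igkc passed without HFD 1 (5.98) and without HFD 2 (5.26), and the other (Ly6d, endothelial-like) without HFD 2 (edgeR adjusted p = 0.0449). In this class 354 genes were at unadjusted p under 0.05, DESeq2 called 2, and the number was 5, 4, 21 and 30 without CTRL 1, CTRL 2, HFD 1 and HFD 2.

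In stem-like cells 0 of 13109 genes passed edgeR, with 1226 at unadjusted p under 0.05 and 26 by DESeq2. The cadherin Cdh6 (log2 1.39), the inhibitor of differentiation Id3 (1.15) and Pdgfrl (0.81) had the smallest p, each at an edgeR adjusted p of 0.168. Without CTRL 1 the number was 250, with Cdh6 (1.33), Id3 (1.31) and Pdgfrl (0.89) among them, and without CTRL 2 it was 20, with Cdh6 (1.47). In mesenchymal-like cells 0 of 8833 genes passed edgeR, with 419 at unadjusted p under 0.05 and 13 by DESeq2. The smallest p were those of Gnrhr (-5.52, edgeR adjusted p = 0.22), Prl (-4.26) and the smooth muscle actin Acta2 (-4.05), both at 0.39, and all 3 stood between 3.9% and 5.2% of their highest class. Without CTRL 1 the number was 5 and without CTRL 2 it was 89, with values of -5.18 and -5.81 (Gnrhr, mesenchymal-like), -3.49 and -4.76 (Prl, mesenchymal-like) and -4.25 and -3.83 (Acta2, mesenchymal-like) in both, and it was 2 without HFD 1.

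Of the 220 tests of lists in classes, 65 passed camera with the preset correlation, 29 higher and 36 lower, and 0 with an estimated correlation (8 at unadjusted p under 0.05) or by fry's directional test (31 at unadjusted p under 0.05). By fry's mixed test, which asks whether genes of a list move in either direction, 24 passed. Cholesterol synthesis and uptake genes were lower in somatotrope-like (median log2 -0.56, camera adjusted p = 2.96e-09) and stem-like cells (-0.39, 4.9e-09), and in endothelial-like (-0.24, 0.00141), thyrotrope-like (-0.16, 0.00248), melanotrope-like (-0.19, 0.0424) and macrophage-like cells (-0.23, 0.0424). The adjusted p ranged from 0.674 to 0.907 with an estimated correlation. In somatotrope-like cells 0 of 25 members passed edgeR and 16 adjusted over the list alone, with Insig1 at -1.13 and Msmo1 at -0.83. Without HFD 2, Insig1 (-1.32, edgeR adjusted p = 0.0271) passed. In stem-like cells 0 of 25 passed and 11 adjusted over the list alone.

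Nuclear genes of oxidative phosphorylation were higher in gonadotrope-like (median log2 0.19, camera adjusted p = 1.18e-18), melanotrope-like (0.19, 1.16e-15) and corticotrope-like cells (0.07, 0.000552) and lower in endothelial-like cells (-0.08, 0.00889). The adjusted p ranged from 0.674 to 0.923 with an estimated correlation. In gonadotrope-like cells 4 of 69 rose and 38 adjusted over the list alone, among them the complex I subunits Ndufb10 (0.36) and Ndufs3 (0.35). Ndufb10 lost its call without CTRL 2 (0.105), HFD 1 (0.156) or HFD 2 (0.0576), and Ndufs3 without CTRL 2 (0.107), HFD 1 (0.121) or HFD 2 (0.133), in edgeR adjusted p. Ribosomal protein genes were higher in gonadotrope-like (0.15, 3.69e-15) and corticotrope-like cells (0.11, 1.63e-09) and lower in somatotrope-like (-0.07, 0.000163), stem-like (-0.10, 0.000402) and mesenchymal-like cells (-0.08, 0.0487), at adjusted p from 0.674 to 0.926 with an estimated correlation. In gonadotrope-like cells 2 of 81 rose, and 23 rose and 1 fell adjusted over the list alone. Rpl21 (0.32) lost its call without CTRL 2 (0.0567), HFD 1 (0.0769) or HFD 2 (0.0647), and another (Rplp0, gonadotrope-like, 0.29) without CTRL 1 (0.0522), HFD 1 (0.139) or HFD 2 (0.0852). Mitochondrial genome genes were lower in endothelial-like (-0.15, 0.0058) and mesenchymal-like cells (-0.21, 0.0258), at 0.772 and 0.892 with an estimated correlation, with mt-Nd6 at -0.28 and -0.41.

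Fatty acid oxidation genes and PPAR targets were higher in stem-like (median log2 0.18, camera adjusted p = 0.000402), endothelial-like (0.19, 0.000542), mesenchymal-like (0.28, 0.00178), gonadotrope-like (0.14, 0.0103) and macrophage-like cells (0.20, 0.0271), each at an adjusted p of 0.674 with an estimated correlation. In gonadotrope-like cells the electron transfer flavoprotein Etfb (0.42) and the trifunctional protein subunit Hadhb (0.42) rose in the fit of all 4 libraries, and 9 rose and 1 fell adjusted over the list alone. In stem-like cells Acot1 was at 0.77, 1 gene passing adjusted over the list alone, and Acot1 passed without CTRL 1 (0.84). Fatty acid synthesis genes were lower in thyrotrope-like cells (-0.19, 0.0228, and 0.674 with an estimated correlation), with Fads2 at -0.59 and Acsl3 at -0.43. Lipid-associated macrophage genes were higher in endothelial-like (0.26, 9e-06), mesenchymal-like (0.39, 0.000103) and melanotrope-like cells (0.24, 0.0267) and lower in thyrotrope-like cells (-0.30, 0.0212), at 0.674 to 0.769 with an estimated correlation. In endothelial-like cells Fabp4 stood at 1.13, passing without HFD 1 (1.33), and the lipid droplet protein Plin2 at 0.79.

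Secretory granule genes were lower in stem-like (median log2 -0.64, camera adjusted p = 7.66e-14), macrophage-like (-0.63, 1.23e-06), mesenchymal-like (-2.41, 3.16e-07) and endothelial-like cells (-0.20, 0.00861), classes that do not make hormones, and higher in melanotrope-like (0.22, 2.18e-06) and corticotrope-like cells (0.10, 0.00156). The adjusted p ranged from 0.674 to 0.853 with an estimated correlation. In stem-like cells 0 members passed edgeR and 14 adjusted over the list alone, with the prohormone convertase Pcsk1 at -1.70 and chromogranin A (Chga) at -1.35. Both are possible free RNA there. They passed without CTRL 1, at -1.95 (Pcsk1, stem-like) and -1.68, and Chga was at 0.12 with doublets kept. Unfolded protein response genes were lower in somatotrope-like (-0.11, 0.00241) and higher in melanotrope-like cells (0.17, 0.000561), at 0.707 and 0.769 with an estimated correlation, with Sdf2l1 (0.40) and Pdia4 (0.42) in melanotrope-like cells. Integrated stress response genes were lower in somatotrope-like cells (-0.28, 0.00132, and 0.674 with an estimated correlation), with Slc3a2 at -0.55 and Ppp1r15a at -0.82 (-1.08 and passing without HFD 2), 0 members passing edgeR and 4 adjusted over the list alone.

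Glucocorticoid response genes were higher in corticotrope-like (median log2 0.27, camera adjusted p = 0.00652), endothelial-like (0.19, 0.00837) and mesenchymal-like cells (0.35, 0.0105) and lower in gonadotrope-like (-0.26, 0.00734) and lactotrope-like cells (-0.18, 0.0175), at 0.674 to 0.872 with an estimated correlation. In lactotrope-like cells the metallothioneins Mt1 (-1.26) and Mt2 (-1.33), both possible free RNA, fell in the fit of all 4 libraries, and 2 rose and 4 fell adjusted over the list alone. In corticotrope-like cells Ddit4 (0.59) and Cdkn1a (0.91) passed adjusted over the list alone, and over all genes without CTRL 1 (0.60 and 0.61) or CTRL 2 (0.60 and 1.30). Leptin and JAK-STAT feedback genes were lower in gonadotrope-like (-0.31, 0.00055), thyrotrope-like (-0.26, 0.00242) and macrophage-like cells (-0.27, 0.0228), at 0.674 to 0.769 with an estimated correlation. Socs3, also in the immediate-early list, fell in gonadotrope-like (-1.91) and thyrotrope-like cells (-1.20), and Pim1 was at -0.65 in gonadotrope-like cells (-0.77 and passing without CTRL 2). There 5 passed adjusted over the list alone.

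Interferon response genes were higher in mesenchymal-like (median log2 0.63, camera adjusted p = 6.49e-13), macrophage-like (0.22, 2.72e-05) and lactotrope-like cells (0.12, 0.0162), at 0.738 to 0.769 with an estimated correlation. In lactotrope-like cells 3 genes passed, among them the MHC class I gene H2-D1 (0.55, possible free RNA), and 4 adjusted over the list alone. Inflammatory genes were higher in mesenchymal-like (0.35, 0.00944) and lower in macrophage-like cells (-0.17, 0.0161), at 0.853 with an estimated correlation, with Il1b at 5.19 and Ccl4 at 4.90, possible free RNA, in mesenchymal-like cells. Antioxidant genes were lower in macrophage-like cells (-0.34, 0.00248, and 0.674 with an estimated correlation), with Slc7a11 at -0.94 and Txnrd1 at -0.85 (-1.28 and passing without CTRL 1). Extracellular matrix genes were higher in mesenchymal-like (0.41, 2.7e-08) and endothelial-like cells (0.33, 7.92e-09) and lower in thyrotrope-like cells (-0.37, 0.0155), at 0.674 to 0.769 with an estimated correlation, with Thbs1 at 0.73 and Col1a2 at 1.33 in endothelial-like cells, both possible free RNA. Insulin and IGF signalling genes were higher in endothelial-like (0.05, 0.0291) and mesenchymal-like cells (0.20, 0.037), at 0.674 and 0.687 with an estimated correlation, with Igfbp4 at 0.83 (1.05 and passing without HFD 2) and Igfbp3 at 0.36 in endothelial-like cells. The list of growth hormone cell regulators had its smallest camera adjusted p in gonadotrope-like cells (0.0917, and 0.772 with an estimated correlation), with Pou1f1 at -1.11 (-2.11 and passing without HFD 2 for Pou1f1, gonadotrope-like) and Esr1 at -0.33 (-0.45 and passing without CTRL 1). The cell cycle list had its smallest in thyrotrope-like cells (0.0712, and 0.756), where Stmn1 rose (0.51) and lost its call without CTRL 2 (0.101) or HFD 2 (0.1), and Hmgb2 was at -0.57.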

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

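The tests of handling on all cells, of handling in stem-like and macrophage-like cells, of the depth of HFD 1 and of free RNA judged from lactotrope-like cells were chosen only after the result was seen. The other 4 tests below were written down before their values were computed. The granulocyte markers used there came from the marker list fixed in advance, though their levels were singled out for the text above only after being seen.

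The lower immediate-early genes of somatotrope-like, gonadotrope-like and thyrotrope-like cells could come from the diet or from handling, since these genes respond to digestion as well. A handling difference acting on all cells alike would have lowered the list in stem-like, endothelial-like, macrophage-like and mesenchymal-like cells too. The criterion for all 4 classes was not met, since endothelial-like (-0.864 to 0.86) and mesenchymal-like cells (-0.863 to 1.34) varied widely over the pairings of libraries. Stem-like and macrophage-like cells stayed at -0.161 or higher against a bound of -0.388. This argues against a difference of the same fold in all cells, or in these 2 classes and the hormone cells. It does not exclude one, since the pairings reuse the same 4 libraries and carry no error, and the bound came from the same data. HFD 2 alone gave -0.661 or lower in all 3 classes. This excludes the depth of HFD 1 for gonadotrope-like and thyrotrope-like cells, with medians of 25460 and 14623 UMIs in HFD 2 against 1683 and 2301 in HFD 1. In somatotrope-like cells depth cannot be excluded, since HFD 2 (10920) was as shallow as HFD 1 (10971). The CTRL 1 and CTRL 2 medians there were 22201 and 14566.5. Free RNA cannot be told apart from a change within the cells, because the list in excluded barcodes ranged from -3.25 to 0.777 over the pairings and lactotrope-like cells lost between 16.2% and 55.6% of what somatotrope-like cells lost. Handling that acted less on other cells stays untested and open beside the diet, since the summed list was higher in stem-like (39120 and 35390 CPM in CTRL) and macrophage-like cells (18030 and 15660) than in the 3 hormone classes and may have responded less there.

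S100a8, S100a9 and the hemoglobin genes may be higher because more blood cells were left in the HFD glands. The other granulocyte markers Retnlg, Csf3r and Cxcr2 had a median log2 difference of 1.38, from 1.33 to 2.16 over the pairings of libraries, as predicted for more blood cells. With Retnlg at 0 CPM in both CTRL libraries, that median was always the larger of the Csf3r and Cxcr2 differences. The smaller was hidden, as for Cxcr2 at 0.2056 CPM in CTRL 2 and 0.3196 in HFD 2. These markers speak for granulocytes alone, and Csf3r and Cxcr2 differed far less than S100a8 and S100a9. The unnamed cluster with monocyte and granulocyte genes held 7, 9, 10 and 16 cells of CTRL 1, CTRL 2, HFD 1 and HFD 2. The log2 ratio of shares was 0.07 for T or NK cell-like and 0.17 for B cell-like cells, and 0.36 and -0.12 with the stricter cell filter. Barcodes mostly of hemoglobin were more frequent in both HFD libraries, as given below. Free RNA is excluded as the source of S100a8 and S100a9, since cells with at least 5 of their UMIs held at least 99.03% of them. Whether the diet brought these cells into the gland or more blood stayed in it was not tested.

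The lower Dbp and Per3 and the higher Arntl of corticotrope-like cells could reflect another time of day at collection of the HFD glands. A shift of the whole gland would have lowered the clock output genes against Arntl and its partners in the other classes as well. Under another time of day at collection of the HFD glands the number of the other 9 classes with a negative difference would be high, and it was 1 with 8 positive. This argues against a shift of all classes in the direction of corticotrope-like cells. The differences carry no error, and those of melanotrope-like (0.0813), mesenchymal-like (0.0913) and macrophage-like cells (-0.0227) were near 0. Those of lactotrope-like (0.832), stem-like (0.692), endothelial-like (0.506) and gonadotrope-like cells (0.504) were larger. Thyrotrope-like cells stood at 0.219, somatotrope-like cells at 0.13 and the whole gland at 0.459. A collection time that shifted most classes the other way, or that acted differently on the classes, was not tested and is not excluded.

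These results were singled out because the diet effect differed between cell classes. By the test of the difference between lactotrope-like and somatotrope-like cells, it was 1.686 for Csrnp1, 0.923 for Btg2, 2.428 for Atoh7, 1.842 for Nog and 1.081 for Tigar on the log2 scale. Rasd1 fell in somatotrope-like (-1.472) and lactotrope-like (-1.087) as well as thyrotrope-like cells (-0.627) and rose in corticotrope-like cells (0.832), with both libraries of each diet on opposite sides, and this difference was not tested. Dbp fell in corticotrope-like (-1.143) and rose in gonadotrope-like cells (0.533), and this difference was not tested either.

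Signals in barcodes outside the kept cells were also singled out. The barcodes under 500 genes held 264 UMIs of S100a8 and S100a9 in HFD 1 and 4 in HFD 2, against 1 in CTRL 1 and 0 in CTRL 2. Barcodes with more than 50% hemoglobin UMIs numbered 36.14 per 1000 kept cells in HFD 1 and 37.1 in HFD 2, against 17.7 in CTRL 1 and 20.13 in CTRL 2.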

How the results depend on the processing

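No alternative reversed a gene that passed. For fits without 1 library this was largely fixed in advance, since the genes that passed had both HFD libraries above or below both CTRL libraries. Of the 83 named genes that passed, 904 of the alternative values stayed past the threshold and 83 did not, most of them without CTRL 2 (17), without HFD 2 (16) or without HFD 1 (10). The shares gave 146 values of the same direction and side of the threshold and 10 reversed ones, and the list tests 63 that stayed and 132 that did not. Fits without 1 library leave a diet with 1 library, which is assumed to vary like the other diet. Of simulated 2-fold changes, 34% were recovered in macrophage-like and 3% in mesenchymal-like cells. The cause of each change below was not tested. Leaving out cells over 100000 UMIs was an alternative chosen after seeing the data.

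Counts of genes passing changed by more than 1.5 times as follows. DESeq2's Wald test gave 214 in the whole gland, 382 in somatotrope-like, 70 in corticotrope-like, 9 in melanotrope-like, 26 in stem-like, 2 in endothelial-like, 23 in thyrotrope-like and 13 in mesenchymal-like cells. Without a low-count filter the counts were 138 in the whole gland, 1 in somatotrope-like, 583 in lactotrope-like, 368 in corticotrope-like, 137 in melanotrope-like, 494 in stem-like, 1444 in gonadotrope-like, 2 in endothelial-like, 183 in thyrotrope-like, 95 in macrophage-like and 202 in mesenchymal-like cells, and 824 for the difference between lactotrope-like and somatotrope-like cells. The stricter cell filter gave 57 in corticotrope-like and 0 in endothelial-like cells, and keeping putative doublets 4 in stem-like and 4 in endothelial-like cells. Leaving out possible free RNA gave 4 in somatotrope-like, 11 in stem-like, 582 in gonadotrope-like and 0 in endothelial-like cells. The number of list tests passing was 0 by camera with an estimated correlation, 0 by fry's directional test and 24 by its mixed test, against 65.

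The replicate numbers are not given as pairs in the sources used here, and deviations of libraries with the same number correlated between -0.175 (somatotrope-like) and 0.32 (endothelial-like) across genes. With a replicate block, 10 genes passed in the whole gland, 13 in somatotrope-like, 318 in lactotrope-like, 179 in corticotrope-like, 24 in melanotrope-like, 337 in stem-like, 69 in endothelial-like, 126 in thyrotrope-like, 17 in macrophage-like and 100 in mesenchymal-like cells, 68 list tests passed camera, and the value for Ghrhr, somatotrope-like, was -0.005. The 13 genes of somatotrope-like cells were all lower, and with the block 4 named genes were past the threshold no longer, at an edgeR adjusted p of 0.0713 (Scnn1b, somatotrope-like), 0.0568 (Ndufs3, gonadotrope-like), 0.0543 (Rpl21, gonadotrope-like) and 0.0766 (Rplp0, gonadotrope-like).

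With 1 library left out, the counts ranged from 6 to 336 in the whole gland, 0 to 86 in somatotrope-like, 50 to 493 in lactotrope-like, 3 to 917 in corticotrope-like, 7 to 195 in melanotrope-like, 0 to 250 in stem-like, 171 to 751 in gonadotrope-like, 4 to 30 in endothelial-like, 51 to 202 in thyrotrope-like, 7 to 15 in macrophage-like and 0 to 89 in mesenchymal-like cells, and from 76 to 643 for the difference between lactotrope-like and somatotrope-like cells. The log2 ratios of shares ranged from -0.276 to 0.645 for B cell-like, -1.325 to 3.401 for Schwann or glia-like, -0.249 to 0.493 for macrophage-like, -0.020 to 0.741 for mesenchymal-like, -0.307 to 0.363 for stem-like and -0.002 to 0.684 for thyrotrope-like cells, and without a change of sign from -0.586 to -0.294 for endothelial-like and 0.146 to 0.262 for corticotrope-like cells. With the stricter cell filter they were -0.121 for B cell-like and -0.151 for stem-like cells.

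Hormone genes that did not pass did so without a low-count filter at -0.334 (Prl, lactotrope-like), 0.232 (Pomc, corticotrope-like), -1.289 (Lhb, gonadotrope-like), 0.232 (Tshb, thyrotrope-like) and 0.232 (Cga, thyrotrope-like), and Tshb also with possible free RNA left out (0.221). With 1 library left out they ranged from -0.665 to -0.060 for Prl, 0.004 to 0.486 for Pomc in corticotrope-like cells, -2.418 to -0.710 for Lhb and 0.119 to 0.333 for Cga in thyrotrope-like cells. Among values that changed sign, the ranges were -0.169 to 0.159 (Ghrhr, somatotrope-like), -0.833 to 0.033 (Ghsr, corticotrope-like), -0.128 to 0.012 (Crhr1, corticotrope-like), -0.226 to 0.087 (Lepr, endothelial-like), -0.077 to 0.011 (Igf1r, stem-like) and -0.208 to 0.065 (Pou1f1, lactotrope-like). With putative doublets kept, the value was 0.117 (Chga, stem-like).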
